A study of Mus musculus with 15 samples.

How the data were processed

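The series measured RNA from snap-frozen livers of WT and Fkbp5 KO mice on a control or an ethanol diet, in 15 libraries prepared from total RNA and sequenced on an Illumina NextSeq instrument. Per the labels, reads were aligned with TopHat to mm9 and quantified with Cufflinks and Cuffdiff, whose versions the labels do not give. The gene table holds FPKM as deposited, for 45861 genes, and the isoform table holds FPKM as deposited, for 119246 isoforms, together with transcript length as deposited. No read counts are in these tables, so that no count model was used. Isoform values summed to the gene value within 1 percent plus 0.01 for 99.98% of genes. In the isoform table there was 1 emptied line. Among gene symbols, 27 had turned into dates, of which 26 were resolved by their position. A further 49 entries share a symbol with another and 11 have a blank gene ID. The labels name mm9, but 99.52% of 41269 uniquely matched symbols overlapped their gene on GRCm38, and 67.25% had both ends within 10 bases, so that positions are given as GRCm38.

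Depth was not listed. It was estimated in 26745 genes of 1 isoform, where equal low fragment numbers give a dense peak of ratios between libraries, and, for the denominators, from the peak of values that 1 fragment gives in genes longer than 1500 bases. The estimates ran from 22120000 to 28610000 fragments, and depths relative to WT control replicate 4 from 0.838 to 1.07. On simulated data the largest error was 0.100% for relative depth and 1.01% for the denominator. At these denominators 1 fragment on a transcript of 1 kb gives between 0.0350 and 0.0452 FPKM. The sums of FPKM ran from 416837 to 790741 per library. Of genes with at least 100 FPKM elsewhere, 7 were listed at 0 in 1 library: Snord47 in WT control replicate 1, Snord49b in WT control replicate 3, Mup1, Mup10, Mup19 and Gm21320 in WT control replicate 4, and Alb in KO ethanol replicate 3. Alb, which every liver expresses, stood between 11793 and 19019 FPKM in the other libraries, and these values of 0 are not read as absence of expression.

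Groups follow the sample titles. WT ethanol replicate 4 is titled WT while its genotype characteristic reads KO; it was kept as WT, and moving it was tried as an alternative. The protocol text gives 4 mice per group and the KO control group has 3 libraries. Sex is not in the labels. Libraries above 10 FPKM of Xist were called Xist-high and the others Y-expressing. Replicates are named as separate mice, so that p-values measure the spread between these libraries.

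Genes with at least 1 FPKM in at least 3 libraries were tested, 13840 in all, of which 10568 are protein coding. Log2(FPKM + 1) of all 15 libraries was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend) as 4 group means, and 5 contrasts were taken: ethanol against control in WT and in KO, KO against WT on each diet, and the interaction. Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adding 1 to FPKM understates fold changes of genes with low values. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. Of 43 lists of cell types, metabolic and stress pathways, contaminating tissues and the genes around Fkbp5, 39 had at least 5 tested members. The list of mitochondrial genome genes matched no symbol. Fkbp5 and Cxcl1 were compared with exact permutation tests, 2-sided. Reads shared between near-identical genes cannot be separated in these tables, so that levels of single Dynlt1, Scd, Gsta, Mup and Amy2a genes are uncertain. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables and plots.

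The groups, comparisons, tests, lists and most alternatives were chosen before the data were examined. So was the rule for naming genes: Fkbp5 and Cxcl1 in every comparison, the called genes with the largest and the most negative fold changes whose groups do not overlap, the called members of each list with the lowest p, and further members where none was called. Called genes with provisional symbols, such as Gm plus digits, were left out by the rule. The text names a subset of the genes that the rule gave, chosen after their values were seen. A result withheld for evaluation is not reported here. The alternatives planned in advance were other pseudocounts, filters, scalings and spread models, library weights, a fit of only the groups compared, a replicate block, the regrouping of WT ethanol replicate 4, 1 entry per symbol, and leaving out each library. A sex term, a restriction to protein-coding genes, zeros taken as missing and the omission of chromosome 17 were chosen after seeing the data. Splits of the libraries into other groups were counted for each comparison.

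The fit was tested on simulated data in 5 simulations per contrast, each with 200 changed genes. With gene spreads drawn from limma's posterior SDs, 5.38%, 4.41%, 4.15%, 7.22% and 5.72% of calls were false in the contrasts in the order above, and 53.7%, 51.6%, 47.8%, 49.9% and 18.8% of genes changed 2-fold were recovered. This version was adopted after a first version with raw residual SDs had been seen; that version gave 4.39%, 5.99%, 6.72%, 4.75% and 5.37% false calls and recovered 54.3%, 43.9%, 46.0%, 51.0% and 21.8%. No call had the wrong sign in either. Camera passed 1 simulated list moved 1.5-fold and 0 of 38 lists left in place. Genes varied independently in all of these simulations, which held no difference between sexes. They cannot show how the list test behaves where members are correlated, and they do not give the share of false calls in these libraries.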

Results

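RNA of snap-frozen mouse liver was sequenced in 15 libraries, which the labels place in a design of genotype by diet. Wild-type (WT) mice and mice carrying a knockout (KO) of Fkbp5, the gene of an immunophilin that binds HSP90 and restrains the glucocorticoid receptor, received either a control liquid diet or a diet with 5% ethanol for 10 days, followed by a gavage of maltose or of 5 g/kg ethanol. Livers were taken 9 hours after the gavage. There were 4 WT control, 4 WT ethanol, 3 KO control and 4 KO ethanol libraries. Of these, 7 expressed Xist and 8 expressed Y-linked genes: 2 of 4 WT control, 2 of 4 WT ethanol, 2 of 3 KO control and 1 of 4 KO ethanol libraries were Xist-high. The files hold FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) without counts. The denominators estimated from the values ran from about 22120000 to 28610000 fragments per library. Between 11701 and 13112 genes reached 1 FPKM in a library. Correlations between replicates, across genes, ran from 0.907 to 0.977. In KO control replicate 1 the signal recognition particle RNA Rn7s1 stood at 183764 FPKM and the 10 highest genes held 59.3% of all FPKM, while the 10 highest genes of each other library held between 19.7% and 28.5%. Rn7s1 and Rn7s2 were listed at 0 in every other library, values that are not read as absence of expression. Whether the RNA of this liver or its quantification differed cannot be told.

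The targeted gene was measured first. Fkbp5 lies on chromosome 17 from 28398753 to 28486149 (GRCm38), and its gene-level and isoform-level values were equal. It stood at 15.2, 9.96, 5.77 and 3.27 FPKM in WT control replicates 1 to 4, at 54.5, 23.9, 47.9 and 45.2 in WT ethanol, at 1.07, 1.56 and 0.351 in KO control, and at 5.41, 4.97, 3.20 and 2.45 in KO ethanol. KO livers thus held 11.6% of the WT mean on the control diet (exact permutation p = 0.0571, the smallest of 35 splits) and 9.34% on the ethanol diet (exact permutation p = 0.0286, the smallest of 70). In WT livers Fkbp5 rose with ethanol from 8.55 ± 5.22 to 42.9 ± 13.2 FPKM (SD, n = 4; log2 fold change 2.31, limma adjusted p = 0.0061, all 4 libraries above the control mean). In KO livers the residual signal went from 0.995 ± 0.610 (SD, n = 3) to 4.01 ± 1.41 FPKM (SD, n = 4), a log2 difference of 1.33 that did not pass (limma adjusted p = 0.0882), and the interaction of genotype and diet was -0.98 with an SE of 0.57.

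The series title names CXCL1 and the Hippo pathway. Cxcl1 encodes a chemokine that draws neutrophils. It averaged 6.03 ± 6.75 FPKM in WT control, 59.8 ± 65.5 in WT ethanol and 7.20 ± 11.5 in KO ethanol (SD, n = 4 each), and 1.73 ± 1.26 in KO control (SD, n = 3). WT ethanol livers ranged widely, at 15.2, 77.9, 144.5 and 1.58 FPKM, while KO ethanol livers stood at 1.75, 24.4, 1.44 and 1.16. The log2 difference with ethanol was 2.33 in WT (exact permutation p = 0.257, higher in 3 of 4 libraries) and 0.82 in KO (exact permutation p = 0.629), and KO ethanol against WT ethanol was -2.59 (exact permutation p = 0.2). None of these differences passed the test across genes, and the smallest limma adjusted p among them was 0.216.

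**Figure D1:**
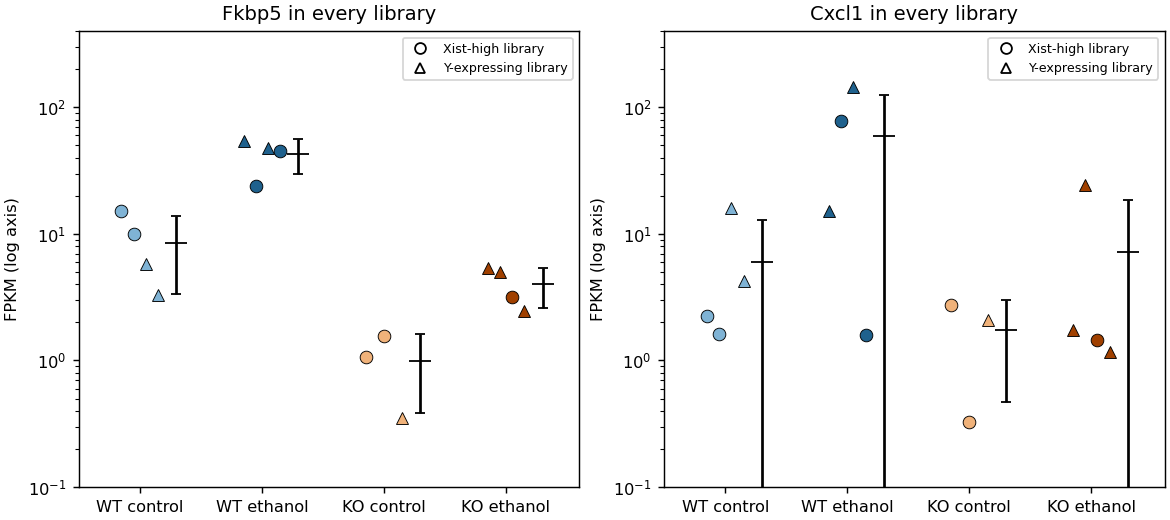
FPKM of Fkbp5 and Cxcl1 on a log axis in each of the 15 libraries, by group (circles, Xist-high; triangles, Y-expressing; bars, mean ± SD, with the lower end off the axis where the SD exceeds the mean). Fkbp5 lay between 23.9 and 54.5 FPKM in the WT ethanol livers and between 0.351 and 1.56 in the KO control livers, and Cxcl1 spread from 1.58 to 144.5 in WT ethanol.

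The first comparison asks what the ethanol diet and binge changed in WT livers. The strongest increase was in Cyp2b10, a cytochrome P450 induced through the nuclear receptor CAR, which rose from 2.35 ± 2.41 to 260.3 ± 238 FPKM (SD, n = 4; log2 fold change 6.10, adjusted p = 0.000581). The metal-binding metallothioneins Mt1 and Mt2 rose by log2 4.93 and 5.90, and the insulin-like growth factor binding protein Igfbp1 rose from 19.2 ± 8.83 to 280.4 ± 163 FPKM. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 1.41 ± 0.68 to 25.8 ± 11.2 FPKM (log2 fold change 3.41, adjusted p = 0.00362). On the other side, the stearoyl-CoA desaturase Scd1 fell from 1156 ± 405 to 231 ± 96.5 FPKM (log2 fold change -2.33, adjusted p = 0.0159; its level is uncertain where reads are shared with Scd3), the clock repressor Nr1d1 fell from 32.0 ± 7.48 to 4.24 ± 2.37 FPKM (adjusted p = 0.00987), and Insig1, a brake on sterol synthesis, fell from 101.7 ± 9.97 to 25.1 ± 17.8 FPKM (adjusted p = 0.037). Each of these genes lay on its side of the control mean in 4 of 4 ethanol libraries.

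Among lists fixed in advance, the glucocorticoid receptor targets rose together, with a median log2 fold change of 1.02 (adjusted p = 2.99e-07, and adjusted p = 0.497 with an estimated correlation). Of 23 members tested, 7 were called higher, 0 lower and 16 not called, and 13 were called higher when adjusted over the list alone. CAR and PXR targets rose with a median of 0.96 (adjusted p = 6.4e-07, and adjusted p = 0.5 with an estimated correlation). Of 22 members tested, 6 were called higher, 0 lower and 16 not called, and 7 higher adjusted over the list alone. Besides Cyp2b10, the P450 reductase Por and Cyp3a13 were among them, at log2 fold changes of 1.98 and 1.63. NRF2 and glutathione genes, an antioxidant programme that shares Mt1 and Mt2 with the glucocorticoid list, rose with a median of 0.99 (adjusted p = 6.16e-05, and adjusted p = 0.717 with an estimated correlation). Of 22 members tested, 6 were called higher, 0 lower and 16 not called, and 8 higher adjusted over the list alone. Acute phase genes rose with a median of 0.94 (adjusted p = 0.000124, and adjusted p = 0.717 with an estimated correlation). Of 27 members tested, 3 were called higher (Orm3, Serpina3m and Il1r1), 0 lower and 24 not called, and 4 higher adjusted over the list alone. Lipid droplet genes rose with a median of 0.41 (adjusted p = 0.0154, and adjusted p = 0.497 with an estimated correlation). Of 15 members tested, 3 were called higher, 1 lower and 11 not called, and 4 higher and 1 lower adjusted over the list alone. Their leading member was Cidec, a protein that fuses lipid droplets, at a log2 fold change of 2.35 (adjusted p = 0.00779, 4 of 4 libraries).

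Lipid synthesis went the other way. Fatty acid synthesis genes fell with a median of -0.93 (adjusted p = 0.000263, and adjusted p = 0.717 with an estimated correlation). Of 21 members tested, 0 were called higher, 3 lower (Scd1, Srebf1 and Elovl5) and 18 not called, and 11 lower adjusted over the list alone. Cholesterol synthesis genes fell with a median of -0.89 (adjusted p = 0.000124, and adjusted p = 0.717 with an estimated correlation). Of 25 members tested, 0 were called higher, 2 lower (Insig1 and Mvd) and 23 not called, and 6 lower adjusted over the list alone. Interferon response genes fell with a median of -0.74 (adjusted p = 7.53e-08, and adjusted p = 0.717 with an estimated correlation). Of 27 members tested, 0 were called higher, 4 lower and 23 not called, and 15 lower adjusted over the list alone. Markers of immune cells lay lower beside them without passing, at medians of -0.88 for MHC class II genes (adjusted p = 0.0887), -0.57 for Kupffer cells (adjusted p = 0.23) and -0.39 for monocytes and macrophages (adjusted p = 0.64), each with 0 members called, over all genes and adjusted over the list alone. Pancreatic acinar markers, which are not liver genes, fell with a median of -1.59 (adjusted p = 3.82e-11, and adjusted p = 0.5 with an estimated correlation). Of 13 members tested, 0 were called higher, 13 lower and 0 not called, and 13 lower adjusted over the list alone. The cytoplasmic ribosomal protein genes had a median of 0.17, or 0.07 with quantile normalization and 0.05 with rescaling to a common sum (adjusted p = 1.88e-07, and adjusted p = 0.717 with an estimated correlation). Of 82 members tested, 1 was called higher, 0 lower and 81 not called, and 0 in either direction adjusted over the list alone. Their library mean gave an exact permutation p = 0.114.

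YAP/TEAD targets, the readout genes of Hippo signalling, had a median of -0.27 and as a list did not pass (adjusted p = 0.0573, and adjusted p = 0.717 with an estimated correlation). Of 15 members tested, 0 were called higher, 2 lower and 13 not called, and 2 lower adjusted over the list alone. The called members were Amotl2, which fell from 7.99 ± 1.54 to 4.01 ± 1.06 FPKM (SD, n = 4; adjusted p = 0.0156), and Cyr61, which encodes a matrix protein and fell by 1.23 on the log2 scale (adjusted p = 0.00927). Of 20 Hippo pathway core genes, 3 were called higher (Tead1, Wwtr1 and Lats1), 1 lower (Amotl2) and 16 not called, and 3 were higher and 1 lower adjusted over the list alone (list adjusted p = 0.357). Tead1, a DNA-binding partner of YAP, rose by 1.52 (adjusted p = 0.0163, 4 of 4 libraries). Among 11 chemokines, 0 were called higher, 3 lower (Cxcl10, Cxcl9 and Ccl27a) and 8 not called, and 4 were lower adjusted over the list alone (list adjusted p = 0.23). Cxcl10, a target of interferon, fell by 1.07 on the log2 scale (adjusted p = 0.0112).

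Across the 13840 genes tested with limma, 1066 were called, 427 higher and 639 lower, and 3564 had an unadjusted p under 0.05. Of 39 lists, 10 passed with the preset correlation and 0 with an estimated one. The count ran from 384 without WT control replicate 2 to 1772 without WT ethanol replicate 4, and was 448, 675 and 509 without WT control replicates 1, 3 and 4 and 423 and 646 without WT ethanol replicates 1 and 3. The genotype characteristic of WT ethanol replicate 4 reads KO while its title reads WT; its Fkbp5 of 45.2 FPKM lay in the WT range, and placing it with KO ethanol gave 1827 genes.

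**Figure D2:**
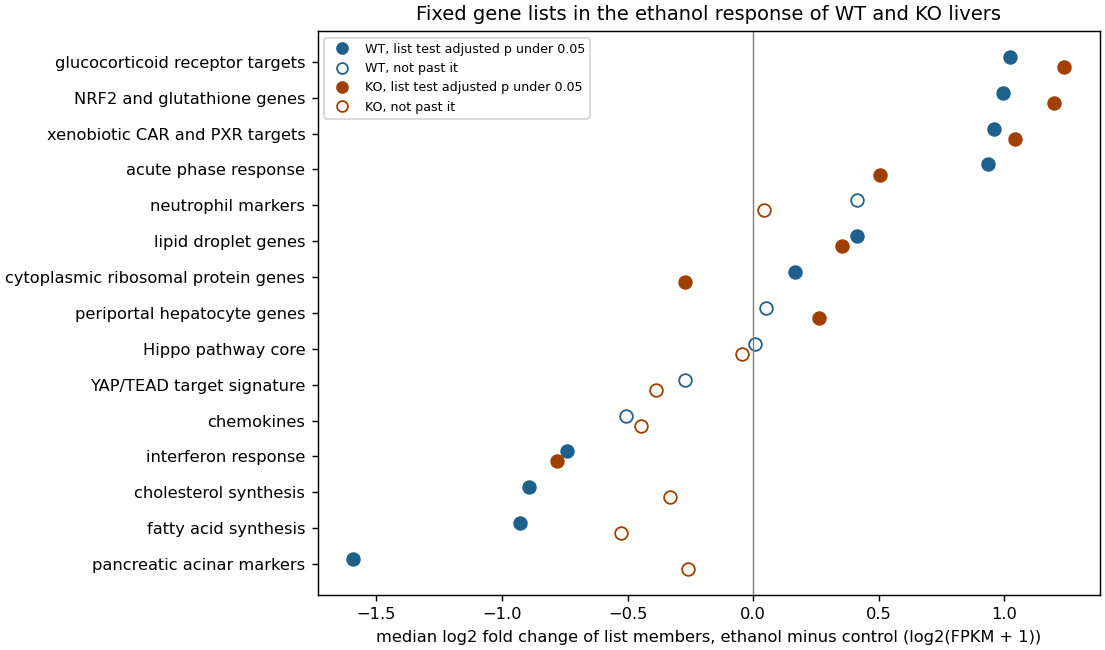
Median log2 fold change (ethanol against control) of 15 gene lists in WT (blue) and KO (brown) livers, filled where the list test had an adjusted p under 0.05 with the preset correlation. Glucocorticoid receptor targets, at 1.02 and 1.24, and CAR and PXR targets, at 0.96 and 1.04, rose in both genotypes by that test (adjusted p = 0.497, 0.147, 0.5 and 0.147 with an estimated correlation), and the ribosomal protein median in KO was -0.27, or 0.08 when a rescaling to a common sum moved all genes, and -0.18 and -0.12 relative to all genes.

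The second comparison asks what ethanol changed in livers lacking Fkbp5. Cyp2b10 rose from 1.13 ± 1.34 (SD, n = 3) to 350.7 ± 79.2 FPKM (SD, n = 4; log2 fold change 7.51, adjusted p = 0.000387). Mt1, Mt2 and Cdkn1a rose by 4.95, 5.53 and 3.63 on the log2 scale, and Ddit4, a stress-induced inhibitor of mTORC1, rose by 3.51 (adjusted p = 0.0134). Fabp1, the fatty acid binding protein of hepatocytes, fell from 4160 ± 676 (SD, n = 3) to 947.0 ± 506 FPKM (SD, n = 4; adjusted p = 0.00946), and Nr1d1 fell by 3.24 on the log2 scale. Each lay on its side of the control mean in 4 of 4 ethanol libraries. The alcohol dehydrogenase Adh4, a gene of retinol and ethanol oxidation, fell by 2.05 in KO (adjusted p = 0.0105) and by 1.96 in WT (adjusted p = 0.00602).

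Glucocorticoid receptor targets rose with a median of 1.24 (adjusted p = 9.63e-13, and adjusted p = 0.147 with an estimated correlation). Of 23 members tested, 8 were called higher, 0 lower and 15 not called, and 13 higher adjusted over the list alone. CAR and PXR targets rose with a median of 1.04 (adjusted p = 4.94e-11, and adjusted p = 0.147 with an estimated correlation). Of 22 members tested, 5 were called higher, 0 lower and 17 not called, and 9 higher adjusted over the list alone. NRF2 and glutathione genes rose with a median of 1.20 (adjusted p = 4.38e-09, and adjusted p = 0.428 with an estimated correlation). Of 22 members tested, 5 were called higher, 0 lower and 17 not called, and 11 higher and 1 lower adjusted over the list alone. Periportal hepatocyte genes rose with a median of 0.26 (adjusted p = 9.87e-05, and adjusted p = 0.408 with an estimated correlation). Of 16 members tested, 3 were called higher, 0 lower and 13 not called, and 4 higher adjusted over the list alone. Asl and Arg1, enzymes of the urea cycle, were among them at 1.55 and 0.96. Lipid droplet genes rose with a median of 0.35 (adjusted p = 0.00147, and adjusted p = 0.147 with an estimated correlation). Of 15 members tested, 2 were called higher, 0 lower and 13 not called, and 3 higher adjusted over the list alone. Acute phase genes rose with a median of 0.51 (adjusted p = 0.000833, and adjusted p = 0.784 with an estimated correlation). Of 27 members tested, 1 was called higher, 0 lower and 26 not called, and 1 higher adjusted over the list alone.

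Interferon response genes fell with a median of -0.78 (adjusted p = 1.06e-06, and adjusted p = 0.784 with an estimated correlation). Of 27 members tested, 0 were called higher, 4 lower and 23 not called, and 14 lower adjusted over the list alone. Beside them MHC class II genes had a median of -0.99 (adjusted p = 0.104), Kupffer cell markers of -0.90 (adjusted p = 0.0599) and monocyte and macrophage markers of -0.57 (adjusted p = 0.68), with 0 members called in each, over all genes and adjusted over the list alone. Cytoplasmic ribosomal protein genes had a median of -0.27 as deposited and 0.08 when FPKM was rescaled to a common sum, which moved all genes, and of -0.18 and -0.12 relative to all genes (adjusted p = 2.08e-09, and adjusted p = 0.784 with an estimated correlation). Of 82 members tested, 0 were called higher, 4 lower and 78 not called, and 17 lower adjusted over the list alone. YAP/TEAD targets had a median of -0.39, with 0 called higher, 1 lower and 14 not called, and did not pass (adjusted p = 0.0577). The called member was Amotl2, which fell by 0.84 on the log2 scale (adjusted p = 0.0322). Of the Hippo pathway core genes 0 were called higher, 1 lower and 19 not called (adjusted p = 0.626), and of the chemokines 0 were called in either direction, with 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.521). Fatty acid synthesis genes, with a median of -0.53, cholesterol synthesis genes, with -0.33, and acinar markers, with -0.26, did not pass in KO livers (adjusted p = 0.214, 0.674 and 0.664).

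With 1 of 3 KO control and 3 of 4 KO ethanol libraries expressing Y-linked genes, limma called 571 genes, 194 higher and 377 lower, out of 3000 with an unadjusted p under 0.05. This balance depended on the scaling: 34.0% of called genes were higher as deposited, 59.7% with median-ratio scaling, 52.2% with quantile normalization and 95.1% with rescaling to a common sum. Of 39 lists, 8 passed with the preset correlation while 0 passed with an estimated one. The count was 298, 95 and 197 without KO control replicates 1, 2 and 3, 162 and 184 without KO ethanol replicates 1 and 2, and 342 without WT control replicate 2. Rescaling FPKM to a common sum, which KO control replicate 1 with its Rn7s1 reads dominates, moved the median of all genes by 0.29. It moved the medians of all genes in the other comparisons by -0.11 for ethanol in WT, -0.30 for genotype on the control diet, 0.10 for genotype on ethanol and 0.40 for the interaction.

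The comparison the series title bears on is whether loss of Fkbp5 altered the ethanol response. The log2 fold changes in WT and KO, which share no library, had a Pearson correlation of 0.692 and a Spearman correlation of 0.691 across 13840 genes, which are not independent replicates. Cyp2b10, Mt1, Mt2, Igfbp1 and Cdkn1a were among 137 genes called higher in both genotypes, where 5.99 would be called by chance, and Nr1d1, Fabp1 and Adh4 were among 206 called lower in both, where 17.4 would be by chance. In opposite directions 1 gene was called. Of the 1066 genes called in WT, 96.06% had the same sign in KO, and of the 571 called in KO, 91.8% had the same sign in WT. The count called alike in both was 343, and was 473 without WT ethanol replicate 4.

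For the difference itself, limma called 0 genes, with 553 at an unadjusted p under 0.05 and a lowest adjusted p of 0.309; the interaction of Cxcl1 was -1.51 with an SE of 1.68. Without KO control replicate 1, 43 genes were called, of which 26 were 5S ribosomal RNA genes and 4 were U3 genes. By list, YAP/TEAD targets (adjusted p = 0.939), Hippo pathway core genes (adjusted p = 0.706) and chemokines (adjusted p = 0.603) did not pass. The acinar markers had a median difference between the genotypes' responses of 1.37, with 0 of 13 called and 13 higher adjusted over the list alone (adjusted p = 2.07e-22, and adjusted p = 0.386 with an estimated correlation). Cholesterol synthesis genes had a median of 0.39 with 0 of 25 called (adjusted p = 9.26e-06, and adjusted p = 0.98 with an estimated correlation), and fatty acid synthesis genes of 0.31 with 0 of 21 called (adjusted p = 0.00362, and adjusted p = 0.98 with an estimated correlation). The ribosomal protein genes had a median of -0.44 as deposited and 0.02 when FPKM was rescaled to a common sum, which moved all genes, and of -0.40 and -0.33 relative to all genes, with 0 of 82 called (adjusted p = 2.28e-46, and adjusted p = 0.386 with an estimated correlation). Adjusted over the list alone, 48 were lower. Pericentral hepatocyte genes had a median of 0.06, or 0.13, 0.20 and 0.52 with median-ratio scaling, quantile normalization and rescaling to a common sum, with 0 called (adjusted p = 0.0491, and adjusted p = 0.501 with an estimated correlation). In these cholesterol, fatty acid and pericentral lists 0 were called adjusted over the list alone. In simulated data the interaction recovered 18.8% of 2-fold and 63.6% of 4-fold changes, and 2.09% of 1.5-fold changes.

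The genotypes were then compared on each diet. The lowest adjusted p on both diets was that of Gm13443, which the naming rule left out because its symbol is provisional. It was higher in KO by log2 1.95 on the control diet and 1.87 on ethanol (limma adjusted p = 2.04e-05 and 1.31e-05). On the control diet, Ctse, an endosomal aspartic protease gene on chromosome 1, was higher in KO livers at 10.0 FPKM against 0.199 in WT (log2 fold change 3.17, adjusted p = 0.00596, 3 of 3 KO libraries). Glo1, the methylglyoxal-detoxifying glyoxalase gene on chromosome 17, stood at 122.0 ± 23.7 FPKM in WT (SD, n = 4) and at 255.6 ± 49.3 in KO (SD, n = 3; log2 fold change 1.06, adjusted p = 0.0284). The dynein light chain copies Dynlt1b and Dynlt1c, on the same chromosome, were higher by 1.04 and 0.97, with levels uncertain because near-identical copies share reads. The genes lower in KO were mostly pancreatic enzymes: Prss2, Cela2a and Cpb1, which encode trypsinogen, an elastase and a carboxypeptidase, changed by -2.36, -2.51 and -1.99 (adjusted p = 0.0284 for Cpb1). Acinar markers had a median of -1.97, with 0 called higher, 7 lower and 6 not called of 13, and 13 lower adjusted over the list alone (adjusted p = 1.02e-53, and adjusted p = 0.021 with an estimated correlation). Their mean per library differed by -2.03 between KO and WT control (exact permutation p = 0.0571, the smallest that 35 splits allow).

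Across all genes on the control diet limma called 25, 10 higher and 15 lower, with 585 at an unadjusted p under 0.05. The balance was 10 higher and 5 lower with quantile normalization, and 2 higher and 22 lower with rescaling to a common sum. Fkbp5 itself, at a log2 difference of -2.13, was not among the called genes (adjusted p = 0.0702). The count was 50 without KO control replicate 1, 1 without replicate 2 and 2 without replicate 3, 2 each without WT control replicates 1, 2 and 3, 2 each without KO ethanol replicates 1 and 2, and 11 without KO ethanol replicate 3. It was 4 with only these groups in the fit and 669 with library weights. Of the lists, fatty acid synthesis genes had a median of -0.28 with 0 called (adjusted p = 0.000181, and adjusted p = 0.825 with an estimated correlation). Cholesterol synthesis genes had a median of -0.22 with 0 called (adjusted p = 0.00319, and adjusted p = 0.996 with an estimated correlation). Ribosomal protein genes had a median of 0.24 as deposited and -0.10 when FPKM was rescaled to a common sum, which moved all genes, and of 0.21 and 0.17 relative to all genes, with 0 called (adjusted p = 2.93e-26, and adjusted p = 0.653 with an estimated correlation). Stellate cell, periportal and pericentral genes had medians of -0.18, -0.15 and -0.08 with 0 called in each (adjusted p = 0.0206, 0.0369 and 0.0446, and adjusted p = 0.825, 0.825 and 0.566 with an estimated correlation). Their medians were -0.18, -0.28 and -0.22 with quantile normalization. They were -0.49, -0.50 and -0.42 with rescaling to a common sum, which moved all genes. In these 6 lists 0 members were called adjusted over the list alone. Among 23 tested genes near Fkbp5, 0 were called higher, 1 lower and 22 not called (adjusted p = 0.416), and the called gene was the colipase gene Clps, itself an acinar marker.

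On the ethanol diet, Ctse was again higher in KO, at 9.81 against 0.0690 FPKM (log2 fold change 3.12, adjusted p = 0.00298, 4 of 4 libraries). Ren1, which encodes renin and lies on the same chromosome as Ctse, stood at 18.8, 5.31, 42.9 and 42.3 FPKM in KO ethanol and at most at 0.273 in WT ethanol (log2 fold change 4.31, adjusted p = 0.00387), and its difference of 1.32 on the control diet did not pass. Fkbp5 itself was lower by log2 -3.12 (adjusted p = 0.00568). Snhg9, a noncoding gene on chromosome 17, was listed at 0 in the 4 KO ethanol libraries and stood at 5.63, 14.9, 3.43 and 11.0 FPKM in the WT ethanol libraries (adjusted p = 0.0106). H2-Bl, a class I histocompatibility gene on chromosome 17, was higher by 1.39 (adjusted p = 0.0114), with reads open to sharing among its family. Glo1 was higher by 0.84 (adjusted p = 0.059).

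In this comparison limma called 14 genes, 11 higher and 3 lower, with 692 at an unadjusted p under 0.05. The count was 4, 8 and 7 without KO ethanol replicates 1, 2 and 3, 0 with WT ethanol replicate 4 placed in KO ethanol (1617 at an unadjusted p under 0.05), 2 with only these groups in the fit, and 6 without chromosome 17. Of the 25 and 14 genes, 7 were called on both diets, all with the same sign, and 3 of them lie on chromosome 17. The 6 lists that passed had 0 called members each, over all genes and adjusted over the list alone. They were stellate cell markers with a median of -0.27 (adjusted p = 0.00737), cholesterol synthesis with 0.21 (adjusted p = 0.0111), acute phase with -0.58 (adjusted p = 0.0212), acinar markers with -0.59 (adjusted p = 1.75e-06), ribosomal proteins with -0.20 (adjusted p = 2.55e-20) and oxidative phosphorylation with -0.12 (adjusted p = 3.9e-05). With an estimated correlation 0 of these 6 lists passed, each at a camera adjusted p = 0.937. The medians of ribosomal proteins and oxidative phosphorylation were -0.12 and -0.04 with quantile normalization and -0.09 and -0.0043 with rescaling to a common sum. Hippo pathway core genes (adjusted p = 0.689), YAP/TEAD targets (adjusted p = 0.759) and chemokines (adjusted p = 0.926) did not pass.

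**Figure D3:**
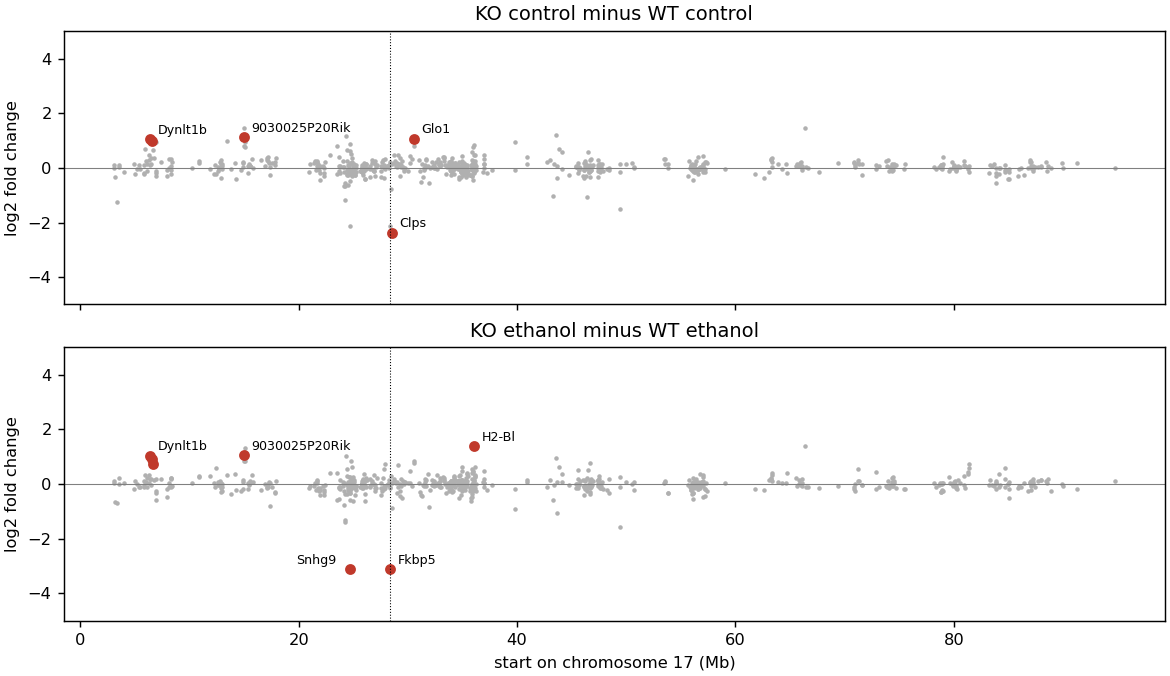
Log2 fold change of KO against WT livers along chromosome 17 (start in Mb, GRCm38) for each tested gene, on the control and the ethanol diet (red, called genes; dotted line, Fkbp5). Glo1 stood at 1.06 and 0.84, and Snhg9 was listed at 0 in the 4 KO ethanol libraries.

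**Figure D4:**
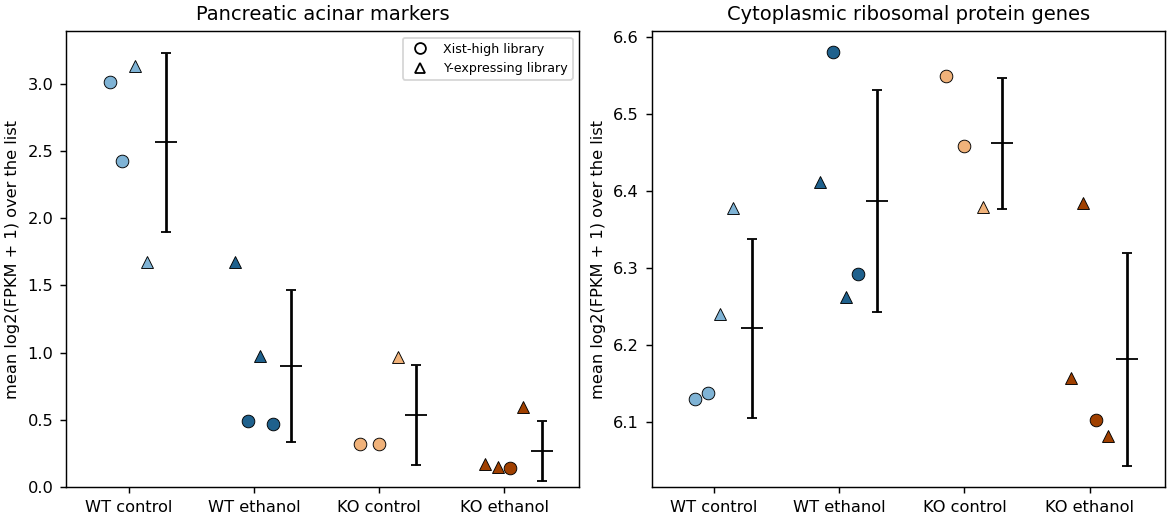
Mean log2(FPKM + 1) over the acinar markers and over the ribosomal protein genes in each library (bars, mean ± SD of the group). The acinar mean was 3.02, 2.43, 3.14 and 1.68 in the WT control livers, and the ribosomal protein difference between KO and WT control had a median of 0.24, or -0.10 when a rescaling to a common sum moved all genes, and of 0.21 and 0.17 relative to all genes.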

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

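The tests of acinar levels in WT ethanol livers and of the ethanol effect by sex were chosen only after the results were seen. Of 236 combinations of a named gene and a group of 4, 18 (7.63%) held a library far from the other 3 by Dixon's test, where chance gives about 1 in 20, and 4 each were in WT control replicate 3 and KO ethanol replicate 4. In WT control, replicate 3 held Lcn2 at 236.9 FPKM (others 3.10 to 6.18), Orm3 at 14.04 (0.969 to 1.78), Hsd3b7 at 123.5 (150.6 to 156.1) and Ren1 at 0.205 (0 to 0.0286). Replicate 4 held Igfbp1 at 5.94 (22.9 to 24.5), Fabp5 at 5.22 (26.97 to 36.83) and Cxcl10 at 1.52 (2.14 to 2.26), and replicate 2 held Lats1 at 6.28 (7.03 to 7.16). In WT ethanol, replicate 4 held Mt2 at 168.0 (2244 to 2261) and Amotl2 at 5.59 (3.35 to 3.63), and replicate 1 held Rnase1 at 0.743 (0.0517 to 0.0966). In KO ethanol, replicate 4 held Dbp at 14.2 (1.05 to 1.46), Dnajb1 at 1.77 (2.97 to 3.18), Clps at 1.72 (0 to 0.0976) and Cpb1 at 0.188 (0 to 0.0245). Replicate 2 held Cxcl1 at 24.4 (1.16 to 1.75) and Gulo at 41.2 (65.4 to 69.0), and replicate 3 held Gsta2 at 12.1 (58.3 to 78.3).

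The response of 5 lists to ethanol differed between the genotypes with the preset correlation and of 0 with an estimated one. Their adjusted p was 0.0491 for pericentral hepatocyte genes, 9.26e-06 for cholesterol synthesis, 0.00362 for fatty acid synthesis, 2.07e-22 for acinar markers and 2.28e-46 for ribosomal protein genes.

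The acinar markers were high in the WT control livers, where Cela2a averaged 13.5 ± 5.71 FPKM (SD, n = 4). In a second list of exocrine genes, outside the fixed list and the called genes, the 9 with over 0.1 FPKM in WT control stood at a median of 9.59 times the KO control level, with 2 of them at 0 in KO control, and all 12 at 9.20 times. Pancreas RNA in the WT control samples may account for these exocrine levels, with the markers at 0.0256%, 0.0152%, 0.0250% and 0.00659% of all FPKM. The 9 genes stood between 0 and 0.335 FPKM in KO control, so that the ratios are imprecise. Islet genes did not show a like rise. Only Ins2 among them passed 0.1 FPKM in WT control, at 0.168 against 0.455 in KO control. WT ethanol livers, which carry Fkbp5, lay below WT control by a median log2 difference of -1.59 (SD over members 0.343), a gap that loss of Fkbp5 cannot account for. It does not decide the difference between genotypes within a diet. On ethanol, where no WT control library enters, the KO library mean lay below WT by -0.637 (exact permutation p = 0.0857), so that a part for Fkbp5 stays open. Why the WT control samples held more was not tested, and the acinar differences of the other groups from WT control may follow from pancreas RNA in those 4 libraries.

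The ribosomal protein genes had an interaction of -0.45 in the library mean, which 0.00531 of the 2450 regroupings of genotype within diet reached (exact permutation p). Genes matched for length and level had 28.2% of the median interaction, which argues against length bias as the whole cause. Median-ratio scaling left 84.4% of it, which argues against scaling as the whole cause, while quantile normalization took the median from -0.44 to -0.23, or from -0.40 to -0.24 relative to all genes, and rescaling to a common sum, which moved the median of all genes by 0.40, took it to -0.33 on that relative scale (0.02 in itself). A differing response of these genes by genotype may account for the pattern, as a hypothesis found and tested on the same libraries. The list test did not pass with an estimated correlation (adjusted p = 0.386), and within each diet the genotypes' library means gave exact permutation p = 0.0571 on the control diet, the smallest that 35 splits allow, and 0.0857 on ethanol.

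The ethanol effect was also compared between Xist-high libraries (4 control, 3 ethanol) and Y-expressing libraries (3 control, 5 ethanol), in a fit with the 4 groups, a sex term and its product with diet. It differed for 4 genes by limma, with 1445 at an unadjusted p under 0.05. These were Cyp2u1, at a difference of -2.50 (adjusted p = 0.0187), Ttc39c, Gm12718 and Hsd3b2. Of the lists, 10 passed with the preset correlation and 0 with an estimated one. Their adjusted p was 0.000233 for stellate cell markers, 0.00845 for cholesterol synthesis, 0.00845 for ethanol oxidation, 0.00136 for CAR and PXR targets, 5.61e-07 for NRF2 genes, 1.02e-11 for glucocorticoid receptor targets, 3.82e-05 for male-biased genes, 5.61e-07 for female-biased genes, 0.000233 for acinar markers and 6.64e-07 for oxidative phosphorylation. Glucocorticoid receptor targets had medians of 0.58 in Xist-high and 1.60 in Y-expressing libraries, NRF2 genes of 0.53 and 1.42, and male-biased genes of -0.58 and -1.85. Genes that are low in Xist-high control livers had little room to fall there. Among male-biased genes, Hsd3b5 stood at 1.83 against 64.5 FPKM in Y-expressing control livers. Of the 4 called genes, Cyp2u1, at 1.65 against 29.1, and Gm12718, at 0 against 4.39, have the same limit. Ttc39c and Hsd3b2 stood higher in Xist-high control livers, Hsd3b2 at 7.56 FPKM. A smaller fall of such low genes is not read as a weaker response to ethanol. How much of the list differences follows from this limit was not tested. The genotypes were not evenly spread over the sexes, and in KO 1 control library was Y-expressing and 1 ethanol library was Xist-high.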

How the results depend on the processing

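The sex term, the restriction to protein-coding genes, zeros as missing and the omission of chromosome 17 were chosen only after the data were seen. No named gene that passed turned its direction under any setting, and of 146 such results between 58 (only the groups compared) and 146 (1 entry per symbol, single zeros as missing) stayed past the threshold, apart from settings that tested fewer genes. Among the named genes 11937 values kept their side, 1112 fell short and 28 passed newly. A further 203 that had not passed moved by at least 1 SE. Among lists 1088 kept theirs, 49 fell short and 32 passed newly. For the list male-biased liver genes, interaction of genotype and diet, a sex term turned the direction, at 0.000251 before adjustment and a limma camera adjusted p = 0.00244. The adjusted p of that list ran from 0.508 to 0.980 in the settings without a sex term. Y-expressing libraries were 2 of 4 in each WT group, 1 of 3 in KO control and 3 of 4 in KO ethanol. Without a sex term the interaction therefore also carries a difference in sex. Whether this alone turned the direction was not tested. FPKM without counts limits what can be said of genes near 1 FPKM.

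The genes called in WT with ethanol numbered 642 with no filter, 438 with rescaling to a common sum, 2248 with library weights, 518 with only the 2 groups, 673 with a replicate block and 1827 with WT ethanol replicate 4 moved. They ran from 384 to 1772 when libraries were left out. In KO with ethanol the counts were 327 with no filter, 4140 with library weights, 97 with only the 2 groups and 303 with a replicate block, and 95 to 754 when libraries were left out. For KO against WT on the control diet they were 6 and 13 with pseudocounts of 0.1 and 10, 4 with the stricter filter, 15 with quantile normalization, 669 with library weights, 4 with only the 2 groups and 14 with WT ethanol replicate 4 moved, and 1 to 50 when libraries were left out. On the ethanol diet they were 9 with a pseudocount of 10, 6 with the stricter filter, 7 with rescaling to a common sum, 2 with only the 2 groups, 9 with a replicate block, 0 with WT ethanol replicate 4 moved (limma, with 1617 at an unadjusted p under 0.05), 22 with a sex term, 7 with protein-coding genes and 6 without chromosome 17, and 4 to 15 when libraries were left out. The interaction gave 1 with no filter and 7 with library weights, and 0 to 43 when libraries were left out. Lists past the threshold with an estimated correlation numbered 0, 0, 1, 0 and 0 in the 5 comparisons, against 10, 8, 7, 6 and 5. With the preset correlation, 4 lists passed for KO against WT control with median-ratio scaling, where 7 had passed as reported. For the interaction with a replicate block 8 passed, where 5 had as reported. Leaving out a library raised some counts of called genes and lowered others. The cause of these changes between settings was not tested. With a sex term, 1066 of 1066, 386 of 571, 24 of 25 and 14 of 14 called genes were kept. Replicate numbers did not pair the libraries: 7 of 21 pairs had a correlation over 0.1 (range -0.329 to 0.444), and 2 of 15 libraries were closest to their own number.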

Other observations

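Dbp, an output gene of the liver clock, fell by 2.67 on the log2 scale in WT (adjusted p = 0.0249) and by 2.73 in KO (adjusted p = 0.0433), and Nr1d2 fell by 0.83 and 0.98, in 4 of 4 libraries each. As a list, circadian genes did not pass in WT, where their median was 0.24 and their mean -0.09 (adjusted p = 0.7), or in KO, where their median was 0.49 (adjusted p = 0.34). In each genotype 0 were called higher, 3 lower and 15 not called. Periportal genes had members higher in WT as well, with 4 called higher, 0 lower and 12 not called, and 4 higher adjusted over the list alone. Their median of 0.05 turned to -0.06 and -0.16 with rescaling to a common sum and quantile normalization, and the list did not pass (adjusted p = 0.0794). Arg1, the last enzyme of the urea cycle, rose from 307.5 ± 19.3 to 605.7 ± 89.1 FPKM in WT (SD, n = 4; adjusted p = 0.00367).

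The partners of Fkbp5 were examined as a list of FKBP and HSP90 co-chaperones. In WT 0 were called higher, 3 lower and 15 not called, and 4 lower adjusted over the list alone (list adjusted p = 0.357). Fkbp4, which encodes a relative of FKBP5 that favours the glucocorticoid receptor, fell by 0.89 in WT (adjusted p = 0.0216) and by 0.86 in KO (adjusted p = 0.0461), in 4 of 4 libraries each. Stip1, which hands clients to HSP90, fell by 0.72 and 0.93. Heat shock genes did not pass (adjusted p = 0.179 in WT and 0.0732 in KO), with Dnajb1 lower by -1.05 and -0.81. Among cell type markers, the collagen gene Col3a1 fell by 1.28 in each genotype (adjusted p = 0.00752 and 0.0146), and stellate cell markers as a list did not pass (adjusted p = 0.133 and 0.0732).

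Cxcl1 was set against 39 lists across the 15 libraries after group means were removed, and 5 relations passed by Pearson's r with Benjamini-Hochberg adjustment (100000 permutations). They were gluconeogenesis genes (r = -0.847, rho = -0.796, permutation p = 0.00016, adjusted p = 0.00624, and 0.0370 for rho), unfolded protein response genes (r = 0.868, rho = 0.846, permutation p = 0.00154, adjusted p = 0.02002, and 0.0370 for rho), and acute phase genes (r = 0.845, rho = 0.811, permutation p = 0.00143, adjusted p = 0.02002, and 0.0598 for rho). Neutrophil markers had r = 0.643 and rho = 0.607 (permutation p = 0.0048, adjusted p = 0.0462, and 0.181 for rho), and pericentral genes had r = -0.704 and rho = -0.546 (permutation p = 0.00592, adjusted p = 0.0462, and 0.205 for rho). Without the 2 libraries farthest in Cxcl1 the same r values were -0.771, 0.855, 0.777, 0.645 and -0.672.

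The tests of read sharing and of the share of called genes on chromosome 17 were chosen only after the results were seen, and so was the sex term in the splits. Of 31 genes called between KO and WT livers on either diet, Fkbp5 left out, 25.8% lay on chromosome 17, against 4.93% of tested genes (Fisher exact p = 9.68e-05, with Dynlt1 copies that share reads counted separately). Pancreatic enzyme genes, Amy2a copies among them, were also counted in the 31, and of these Clps lies on chromosome 17. The share was not computed without them. As counted, the share on chromosome 17 argues against a loss of Fkbp5 acting evenly over the genome as the whole source. Among uncalled genes, the KO minus WT differences at the 2 diets had a correlation of 0.544 on chromosome 17 and at most 0.362 on another autosome, and 0.501 against 0.277 with a sex term. This is consistent with variants of another strain carried along with the targeted allele, a candidate explanation for Glo1, Dynlt1b and H2-Bl. Reads shared between near-identical copies may account for the Dynlt1 calls and stay open for others: 71.9% of 32 called genes had no other called gene of the same symbol stem, but 18 had a provisional name or another gene of that stem in the table.

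Other splits of the same libraries were counted. For ethanol in WT, 1 of 35 splits, the real one, gave as many as 1066 genes, and the highest other gave 24. For ethanol in KO it was also 1 of 35, with 571 genes against 80 in the highest other, or 485 against 152 with a sex term. Both counts argue against a grouping by chance. The splits cannot exclude it, since 1 of 35 is the smallest share that they can give. For KO against WT on the control diet the splits alone do not exclude chance for the count, since 2 of 35 gave 25 or more. The highest other, 91, was the split of the libraries by sex, a structure of these samples. With a sex term the real split gave 29 and the highest other 24. On the ethanol diet the splits alone do not exclude it either, with 14 genes against 33 in the highest other and 3 of 35 splits as large. A sex term did not change this, with 22 genes against 40 in the highest other and again 3 of 35 as large. Of the 25 and 14 genes, 7 were called with the same sign on both diets, which share no library, where 0.0112 would be by chance. The 0.0112 takes the comparisons as independent, but both used the same estimate of each gene's spread, and Dynlt1 copies among the 7 share reads. The overlap was not counted in the other splits, so that it does not decide whether those 7 reflect a grouping by chance. For the interaction 47 of 100 regroupings reached the 553 genes at an unadjusted p under 0.05, the highest gave 2455, and chance cannot be excluded.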
